A study of Chlamydomonas reinhardtii with 14 samples.

How the data were processed

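Small RNAs of the unicellular green alga Chlamydomonas reinhardtii were sequenced in 12 libraries, and genomic DNA in 2 libraries. Total RNA was extracted with Trizol and its small RNA fraction isolated with mirVana, per the labels' protocols. The genomic DNA came from vegetative cells of the strain cw15_325arg and was cut with micrococcal nuclease, and part of it was immunoprecipitated with an antibody against methylcytosine, per the labels' protocols. Each deposited list holds distinct read sequences that the authors had matched to the Chlamydomonas genome after removal of the 3′ adaptor, with a read count for each sequence, per the file headers. The name of the alignment tool PatMaN stands in the deposited names. Its settings, the number of mismatches allowed and the genome build are not given in the sources used here. For the first vegetative cw15_325arg library, the deposited data also hold all reads after adaptor removal, without a filter on alignment, per the labels.

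The plan kept count-model tools for deposited numeric columns of counts. No deposited column passed as one, so these tools were left out, although counts tallied from the headers could have been given to them. Reads were tallied from the headers into a matrix of distinct sequences by library. No genome was used here, so sequences were not placed in loci, and their positions, overlapping genes and annotation classes were not analysed. The features are therefore distinct sequences of 18 to 28 nt, the fallback set before the data were examined. Levels are in CPM, relative to all reads of 18 to 28 nt in a library. A sequence was tested when it reached 10 CPM in at least 2 libraries, which kept 6563 of 389618 sequences. These held between 87.1% and 95.4% of the reads of each library. The tested sequences fell into 1923 families that share 16 bases in a row on the same strand, so neighbouring sequences are not independent. Reads from the 5′ ends of 18S, 5.8S and large subunit ribosomal RNA were recognised by conserved starting motifs, which were chosen after the data were seen and stand for the planned annotation classes.

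Differences were tested with limma 3.58.1 in R 4.3.3, on log2 CPM with voom weights and a pseudocount of 0.5 reads. The fit had 9 coefficients, 1 for each of the 9 groups, and Benjamini-Hochberg adjustment over the 6563 sequences at a threshold of 0.05. The spread came from the 3 groups with 2 libraries, which gave 3 residual degrees of freedom and 4.21 prior degrees of freedom. Groups of 1 library were assumed to vary like those pairs. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Of 8 comparisons, 7 were fixed before the data were examined. The comparison of NO- with cc124- over vegetative and starved libraries was added after the data were seen. Named sequences followed a rule fixed in advance. In each comparison these are the 10 largest rises and 10 largest falls among sequences that passed the test, did not overlap between groups and averaged at least 50 CPM in the higher group. The rule adds up to 5 sequences of 21 nt that passed, or, where fewer than 5 passed, the 5 with the smallest p. It also names the 3 most abundant sequences, and for methylation the 5 highest and 5 lowest ratios among the 200 most abundant sequences. Libraries without a replicate were compared by ratio alone, over sequences with at least 50 CPM in either library.

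A group with no read for a sequence was given a floor of 3 counts over its pooled reads, and the fold is then a lower bound. In comparisons of 1 library with 1 library the floor was 3 counts of that library. For groups with few reads, the ratio of pooled reads is given with an exact 95% interval. Shares carry exact Clopper-Pearson 95% intervals. All intervals and floors cover counting error only, since reads made by PCR are not independent molecules. Floors per library lay between 0.476 and 3.20 CPM.

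The fit was tested on simulated counts with 100 sequences changed 4-fold and 100 changed 16-fold. With the same spread in every group, it recovered between 86 and 100 of the 16-fold changes across the 8 comparisons, with between 1 and 58 false calls in each. With the spread measured in each pair, it recovered 0 in 7 comparisons. In the comparison of cw15_325arg with the other strains it then made 615 false calls among 669. The SD of log2 levels was 2.95 in the cw15_325arg pair, 0.548 in the starved cc124- pair and 0.509 in the gamete pair. Without the libraries of cw15_325arg, the fit recovered between 71 and 100 of the 16-fold changes in the 6 comparisons that do not use that strain. A first version of this test also changed very abundant sequences, which shifted the totals and produced many false calls. The changed sequences were then limited to moderate levels, averaging at least 50 CPM over whole-cell libraries. The test therefore covers neither large changes in abundant sequences nor changes in sequences at lower levels.

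For methylation, the central 18 bases of each tested sequence were counted on either strand in the DNA reads, which are 25 nt long. The measure is the log2 ratio of immunoprecipitated (IP) to input reads per library total, with a pseudocount of 1 read and at least 10 input reads. Its median was set against 10000 random sets of 18-mers from the input reads. The random 18-mers were first drawn from both DNA libraries. That pool was biased toward IP reads and was replaced after its result had been seen. Sites with few reads in a random part of the input, called low-copy here, were pooled and counted in the rest of the input. Their copy number in the genome was not measured. They ranked lower against that first pool. Lists of sequences by length were tested with camera in limma, with a preset correlation of 0.01 and again with an estimated one. Alternatives covered scaling, filters, pseudocounts, the limma-trend method, read length, overlap families and the removal of single libraries. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and the R package data.table in version 1.17.8, and plots matplotlib 3.10.9.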

Results

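The series profiled small RNAs of Chlamydomonas reinhardtii in 3 strains and through the sexual cycle, and measured methylation of genomic DNA. The 12 small RNA libraries came from vegetative NO- cells (n = 1), NO- gametes induced by nitrogen starvation (n = 2), vegetative cc124- cells (n = 1), nitrogen-starved cc124- cells (n = 2), vegetative cw15_325arg cells (n = 2), cw15_325arg nuclei (n = 1) and zygotes of R3+ with NO- at 30 min, 2 h and 6 h (n = 1 each). cc124- is a standard laboratory strain, and cw15 strains lack a normal cell wall. Aligned reads per small RNA library ranged from 959867 to 6519662, with 3646 to 148905 distinct sequences. The nuclei library was the least diverse, and 9.65% of its distinct sequences were seen once. The second cw15_325arg library had 7.08% seen once. Whether sequences with few reads had been removed from these 2 lists is not given in the sources used here. The other 10 small RNA libraries had between 55.3% and 71.7%. The DNA libraries held 1420115 input reads and 1310455 reads after methylcytosine immunoprecipitation.

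Small RNAs of 21 nt dominated all 12 libraries. In the 11 whole-cell libraries their share of aligned reads had a median of 56.5% and ranged from 44.3% to 68.6%, and in nuclei it was 58.3%. Most 21 nt reads began with T or A, with medians of 52.3% and 42.8%, while C and G had medians of 2.78% and 1.53%. T was the most frequent first base in 6 libraries and A in the other 6, among them the nuclei and the 3 zygote libraries. In zygotes at 6 h, A and T were level at 46.7% each. With each distinct 21 nt sequence counted once, T led in every library, with 50.8% against 30.8% for A in nuclei. The lead of A thus holds for reads and not for distinct sequences. The most abundant sequence, TACCTGGTTGATCCTGCCAGTAG, is the 5′ end of 18S ribosomal RNA and made up most 23 nt reads in 10 of 12 libraries. The second, AGCAGACCCGGGACGCAGTGC, a 21 nt sequence, was abundant in cc124-, nuclei and zygotes. The third, AGGACGAAGAGCTTCTTGATT, reached 87397 CPM in vegetative NO-, and ranged from 76.9 CPM in the first cw15_325arg library to 31646 CPM in the second.

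**Figure D1:**
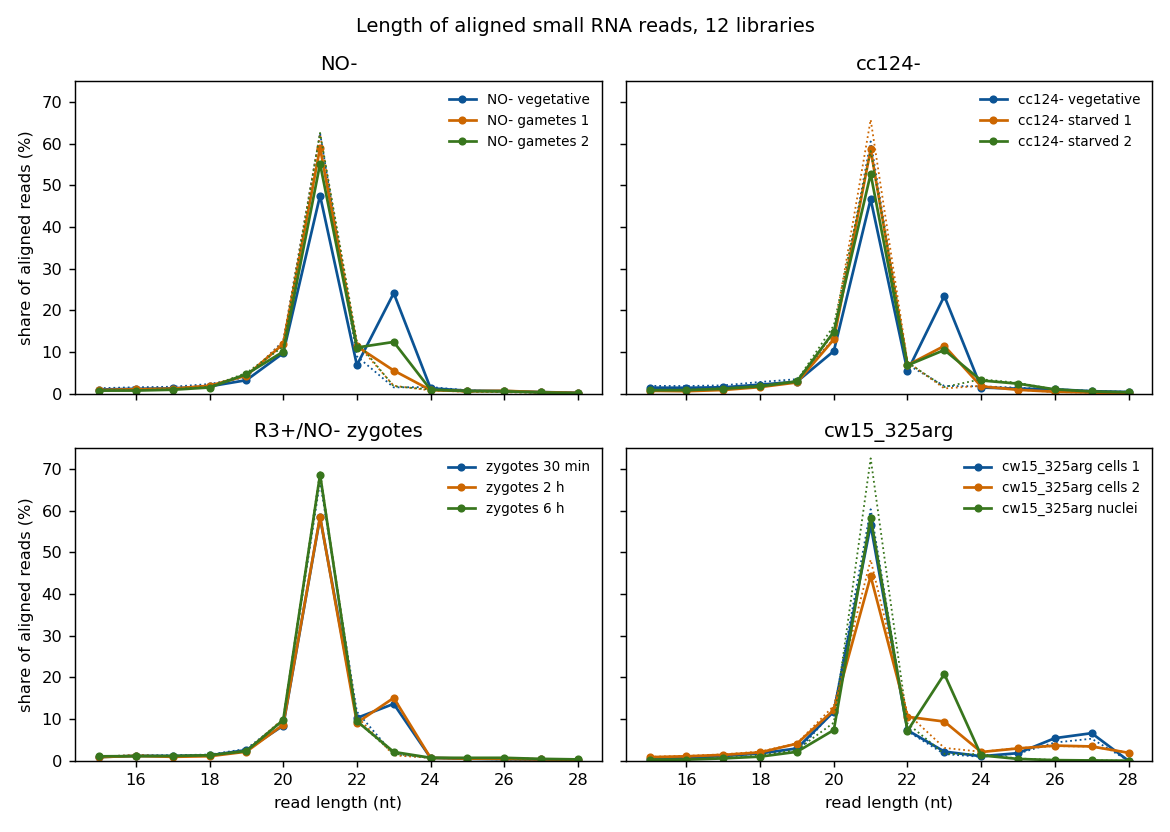
Share of aligned reads (%) by read length (nt) in 12 small RNA libraries, for all reads (solid lines) and without the 5′ ends of ribosomal RNAs (dotted lines). The 21 nt class is the highest point of every library, and the 23 nt peak is lost from the dotted lines.

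Reads from the 18S 5′ end took 23% of aligned reads in vegetative NO- and 22% in vegetative cc124-. In starved cc124- they took 10.3% and 9.04%, and in NO- gametes 3.73% and 10.8%. The mean was 8.49% ± 3.26 (SD, n = 4) in the starved cells of both strains and 22.5% ± 0.677 (SD, n = 2) in their unstarved cells. A two-sided exact permutation test gave p = 0.0667, the smallest value 15 splits allow, and 0.0889 after adjustment over 4 measures. Reads of 21 nt averaged 56.4% in starved and 47.1% in unstarved cells of these strains, with the same exact p and adjusted p. Without the rRNA ends in the totals the 21 nt shares were 62.2% ± 3.08 (SD, n = 4) and 61.5% ± 1.40 (SD, n = 2), exact permutation p = 0.733, a check added after the data were seen, so that difference goes with the 18S share. These comparisons left out the vegetative cw15_325arg libraries, whose strain has no starved library. Their 18S shares were 0.418% and 6.52%, both below the starved mean, and their 21 nt shares were 56.5% and 44.3%. Reads from the 5.8S 5′ end took between 0.146% in nuclei and 2.55% in the first cw15_325arg library. Reads from the 5′ end of the large subunit reached 4.09% and 0.762% in vegetative cw15_325arg, and at most 0.0224% in the other 10 libraries.

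**Figure D2:**
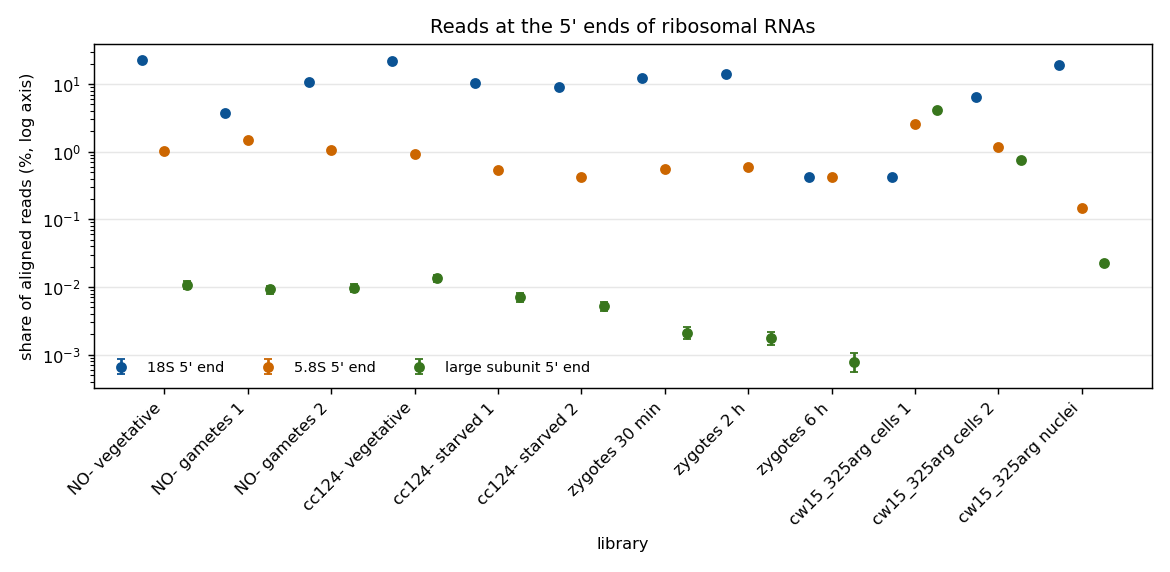
Share of aligned reads (%, log axis) at the 5′ ends of 18S, 5.8S and large subunit ribosomal RNA in each library, with exact 95% intervals, most of which are smaller than the points. The 18S end falls from 14.0% in zygotes at 2 h to 0.430% at 6 h.

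The strains NO- and cc124- made different sets of small RNAs. TGTCGAGCAGGCCGCGATCGG averaged 3480 CPM ± 197 (SD, n = 3) over vegetative cells and gametes of NO-, and had no read in the 3 cc124- libraries, at least 8912-fold lower. AGACAGAGACGGGCGTAAGAT averaged 835 CPM ± 146 (SD, n = 3) in NO- and was also absent from cc124-, at least 2140-fold lower. In the other direction, TTGGGCGGCGTTGTAAGATT averaged 24028 CPM in cc124- and 0.843 CPM in NO-, and AGAACAGGCGTTCGACGGACA averaged 9870 CPM ± 1867 (SD, n = 3) in cc124- and 0.601 CPM in NO-. TCGGAGAAGCGGGTAGCTGA averaged 1999 CPM in cc124- with no read in NO-, at least 4467-fold higher.

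Over vegetative and starved libraries of both strains, 622 sequences were higher and 857 lower in NO- at an adjusted p under 0.05 by limma, and 1580 passed by limma-trend. Of the limma calls, 373 of the higher and 434 of the lower sequences were 21 nt long, as were 2852 of all 6563 tested. Of the sequences that passed, 135 higher and 300 lower ones met the full rule for named sequences. AATGCTCGAAATTTCCGCGCC had 13001 reads in NO- and 2 in cc124-, a ratio of 7453 with a 95% interval of 2063 to 61545. TTTAGGACAGCAGGACGCGA, TAGGACAGCAGGACGCGAGC and TTAGGACAGCAGGACGCGAGC overlap and averaged 3672, 2167 and 2115 CPM in NO-. TTATAGACGGCATTGAAATG and the overlapping ATTATAGACGGCATTGAAATG averaged 2874 and 1941 CPM in cc124-. TAGAGGAGAAGATTAAACACAA and AGGGAGGGCAACATGAAGGGT averaged 1022 and 939 CPM in cc124- and had no read in NO-. All 21 named changes passed the test in each alternative run for them. Which strain had more calls depended on the setting. Without the first vegetative cw15_325arg library 1227 were higher and 1012 lower in NO- (2239 in all), without the second 1238 and 1011 (2249 in all), and without all 3 cw15_325arg libraries 1185 and 963.

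Vegetative NO- and cc124- were also compared directly, with 1 library each and no test. Of 1502 sequences with at least 50 CPM in either library, 150 were over 10-fold higher and 298 over 10-fold lower in NO-. TGCCCTCGGGACATCCGGTAG had 1322 reads in NO- and 0 in cc124-, at least 525-fold higher by the floor of that library. TCACGGACAATGGACGGCATA had 3583 reads in cc124- and 0 in NO-, at least 1002-fold lower. Between the starved cc124- pair 8 of 1284 sequences, and between the gamete pair 8 of 1411, were over 10-fold apart. In the cw15_325arg pair it was 530 one way and 607 the other, of 2050.

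Sequences specific to each strain were then followed through all libraries, by a rule chosen after the data were seen. There were 158 sequences with at least 50 CPM in all 3 cc124- libraries and at most 1 CPM in all 3 NO- libraries, and 79 with the reverse. Above 1 CPM, 72 of the 79 NO- specific sequences were found in each vegetative cw15_325arg library, and all 79 in each zygote library. Of the cc124- specific sequences, 1 and 2 were found in the vegetative cw15_325arg libraries, 79 in cw15_325arg nuclei, and 39, 39 and 34 in zygotes at 30 min, 2 h and 6 h. In zygotes, the NO- specific sequences stood at a median of 0.362, 0.338 and 0.268 of their level in gametes at the 3 times. Over all 994 sequences above 50 CPM in gametes the median ratios were 0.655, 0.601 and 0.561.

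**Figure D3:**
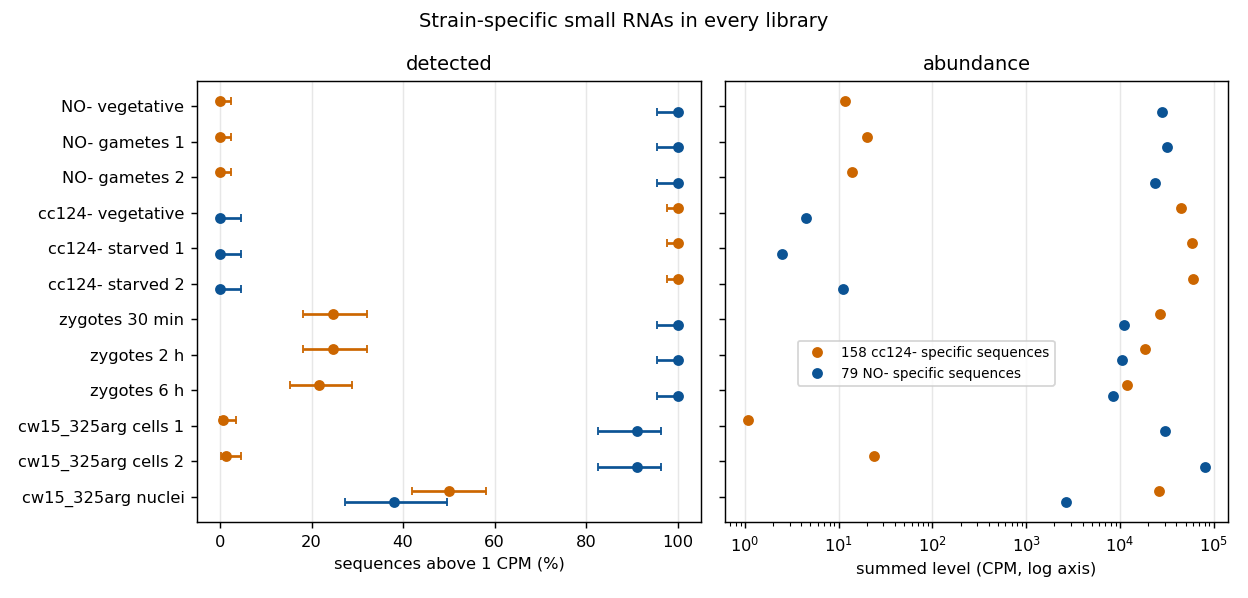
Left, share of strain-specific sequences above 1 CPM (%, with exact 95% intervals) in each library; right, their summed level (CPM, log axis). Vegetative cw15_325arg cells hold 91.1% of the NO- specific sequences in both libraries and at most 1.27% of the cc124- specific ones.

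No single sequence passed the limma test between NO- gametes and vegetative NO- cells, nor between starved and vegetative cc124- cells, where limma-trend called 26. In NO- gametes, AGGCCAGGAGGCATTCGTCTGC averaged 12.7 CPM against no read in vegetative cells, at least 7.92-fold higher, without passing. In starved cc124- cells, TTCGGCGACGGTGAAATACCACT averaged 17.4 CPM ± 10.2 (SD, n = 2) against no read, at least 12.9-fold higher, and TTCGGCGACGGTGAAATACCACTACT had 380 reads against 3. The first of these had no read in vegetative NO- either, and 8.23 and 14.0 CPM in the gamete libraries. The longer sequence contains the shorter one, and whether they come from ribosomal RNA beyond the recognised 5′ ends was not tested. CACCCGACTAAGGATACATCCGCCT went the other way, with 34.9 CPM in vegetative cc124- and no read in starved cells, at least 63.5-fold lower.

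For gametes, limma called 0 sequences, 46 had an unadjusted p under 0.05 where 328 would be expected by chance, and limma-trend called 0. For starved cc124- cells limma called 0, with 40 at an unadjusted p under 0.05, and limma-trend called 25 higher and 1 lower. For the mean effect of starvation over both strains limma called 0, with 98 at an unadjusted p under 0.05, and limma-trend called 8 higher. The difference between the gamete response and the starvation response gave 0 calls, 8 at an unadjusted p under 0.05 and 0 by limma-trend. That difference is confounded with strain, since gametes were NO- and starved cells cc124-. These zeros say little, because a simulation with the measured spreads recovered 0 of 100 changes of 16-fold. Without the cw15_325arg libraries limma called 0 for gametes, 0 for starved cc124-, 0 for their difference and 3 higher for the mean of both strains, where the simulation recovered 100 of 100 changes of 16-fold for all but the difference (71 of 100). Of 100 changes of 4-fold it recovered 42 for gametes, 38 for starved cc124-, 86 for the mean and 11 for the difference, so smaller changes can be missed. The simulated changes lay in sequences averaging at least 50 CPM, so recovery at lower levels was not tested. Of the 6563 tested sequences, 2162 reached 50 CPM in 2 libraries. With only the first or only the second vegetative cw15_325arg library left out, the mean of both strains also gave 3.

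Zygotes carried abundant small RNAs that were far lower in NO- gametes, the gametes of their minus parent, or had few or no reads there. AGCAGACCCGGGACGCAGTGC averaged 102340 CPM over the 3 zygote times and 127 CPM ± 42.3 (SD, n = 2) in gametes, with a pooled ratio of 815. AGAACAGGCGTTCGACGGACA averaged 9468 CPM ± 3484 (SD, n = 3) in zygotes and had 3 reads in gametes, a ratio of 15002 with a 95% interval of 5133 to 72747. AGCAGAACAGGCGTTCGACGG and TCGGAGAAGCGGGTAGCTGA averaged 2569 and 1368 CPM in zygotes with no read in gametes, at least 4137-fold and 2202-fold higher. These 4 sequences were also abundant in cc124-.

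By limma, 279 sequences were higher and 2 lower in zygotes than in gametes at an adjusted p under 0.05. Of the higher ones 160 were 21 nt long, as were 2852 of all 6563 sequences tested. They fell into 102 overlap families, and 168 of the 279 stayed at or below 1 CPM in the 9 libraries that were not zygotes. Among these were TGTAGGTAGGCGGATAGGTAGG, at 962, 739 and 268 CPM at 30 min, 2 h and 6 h, the overlapping TGTAGGTAGGCGGATAGGTAG, and TACGAGTAGGAGCCATGGCCA at 514, 346 and 204 CPM. TAGAGGAGAAGATTAAACACA, TAGAGGAGAAGATTAAACACAA and TGAGGTAGAGGAGAAGATTAA overlap and averaged 2346, 729 and 373 CPM in zygotes. TCGGAGAAGCGGGTAGCTGAG and TCGGAGAAGCGGGTAGCTGAGG averaged 477 and 512 CPM. CACCCTGTCACTGAACCCGCC fell from 89.3 CPM ± 33.9 (SD, n = 2) in gametes to 3.24 CPM in zygotes. The adjusted p of the 10 largest rises lay between 0.00948 and 0.0112 with limma. For the 168 sequences, the pairs that give the spread held few or no reads. Their p-values therefore measure no variation between libraries in which these sequences are present.

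A simulation of this comparison made 58 false calls among 237 with the same spread in every group, and recovered 0 of 100 changes of 16-fold with the measured spreads. The count of calls changed when libraries were left out. It fell to 0 without either gamete library and to 20 without either starved cc124- library, and rose to 1351 or 1444 without the first or second vegetative cw15_325arg library. It was 176 without the 30 min and 166 without the 2 h library, and with all 3 cw15_325arg libraries out 537 were higher and 875 lower.

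**Figure D4:**
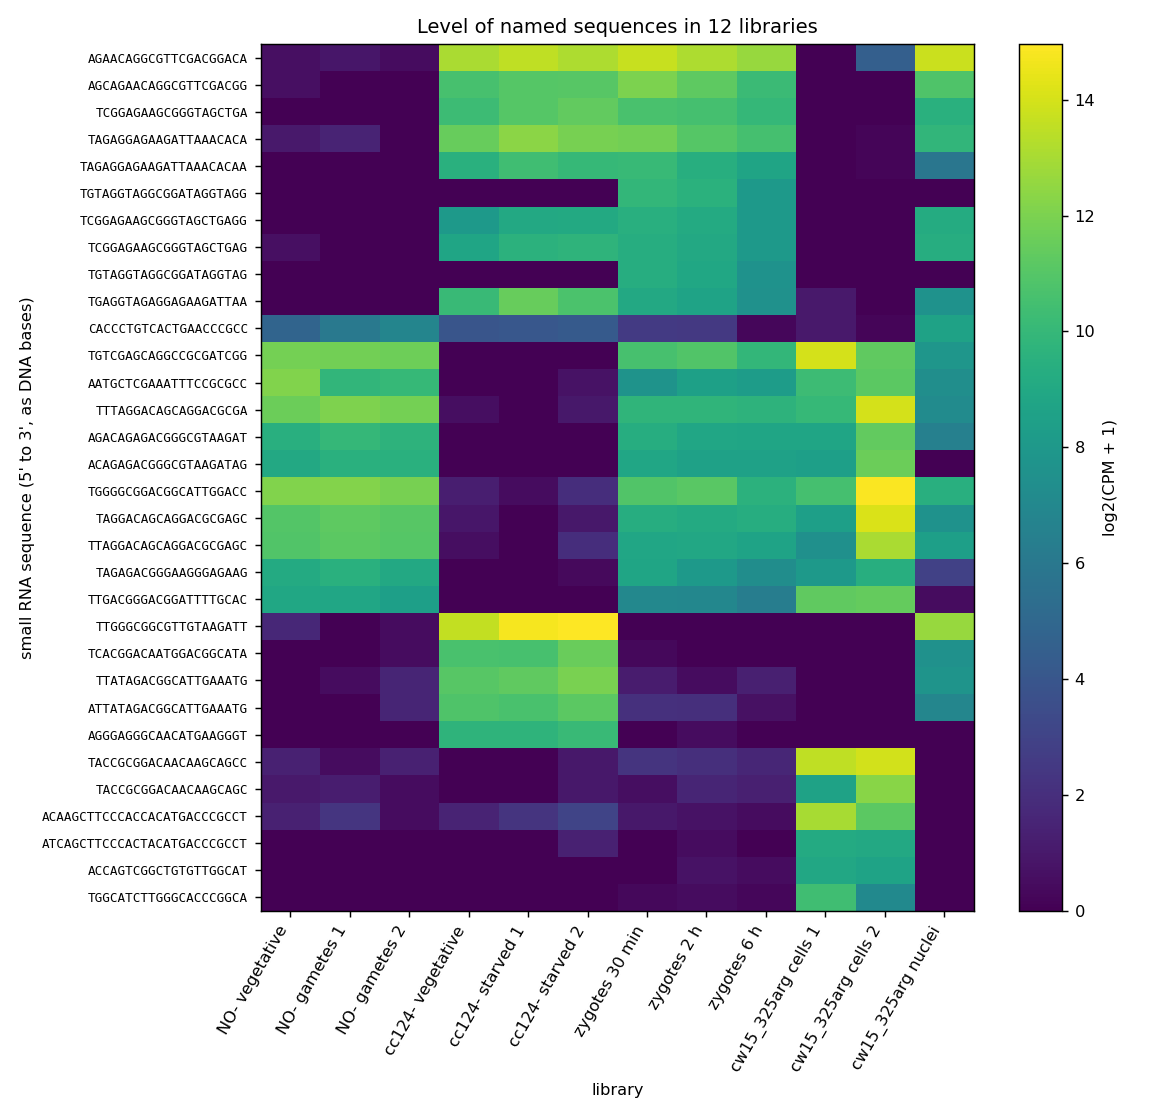
Level of named sequences (rows, as DNA bases) in 12 libraries (columns), coloured by log2(CPM + 1). The upper 10 rows rose and the next fell in zygotes, the middle rows differ between NO- and cc124-, and the lowest rows were high in vegetative cw15_325arg cells and absent from their nuclei.

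Between zygotes at 30 min and 2 h the populations were alike, and by 6 h they had diverged. Of 1208 sequences with at least 50 CPM, 3 were over 10-fold higher and 0 over 10-fold lower at 2 h than at 30 min. From 2 h to 6 h, 313 of 1629 sequences were over 10-fold higher and 12 over 10-fold lower. CAGAACAGCGGCGATAAAGGA had 1298 reads at 6 h and 0 at 2 h, at least 407-fold higher by the floor of that library. GGCGCATCGACGGCTTCGTAA and GGCGCATCGACGGCTTCATAA had 1093 and 1089 reads against 0. AGGGCCTGGCGGAGCAGGCGGC had 2548 reads against 2, a ratio of 1200 with a 95% interval of 332 to 9912. TCAATGGTAGCCAGTCTGCGC went from 5.15 CPM at 30 min to 82.1 CPM at 2 h. The 18S fragment TACCTGGTTGATCCTGCCAGTAG went from 143971 CPM at 2 h to 4439 CPM at 6 h, 32.4-fold lower, and TGGCAGTGACGAAACAATGAA from 119 to 4.32 CPM. With 1 library at each time there is no replicate check, and these ratios compare libraries.

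Vegetative cw15_325arg cells made small RNAs that were almost absent from both other strains. TACCGCGGACAACAAGCAGCC averaged 13750 CPM ± 3025 (SD, n = 2) in cw15_325arg and had 3 reads in vegetative NO- and cc124- together, a ratio of 20982 with a 95% interval of 7179 to 101743. ACCAGTCGGCTGTGTTGGCAT averaged 459 CPM ± 71.3 (SD, n = 2) with no read in the other strains, at least 628-fold higher. Longer sequences among the named rises were ATCAGCTTCCCACTACATGACCCGCCT at 536 CPM ± 26.4 (SD, n = 2) and ACAAGCTTCCCACCACATGACCCGCCT at 8279 and 2308 CPM. TGCGGTGAATCATGATAACTTCACGAA and ATCATGATAACTTCACGAA averaged 321 and 235 CPM in vegetative cells of the other strains and had no read in cw15_325arg, at least 774-fold and 566-fold lower. They overlap, and averaged only 15.5 and 34.7 CPM in starved cc124- and 82.5 and 39.0 CPM in NO- gametes. Whether they come from ribosomal RNA was not tested. TTATGGACAATTCACGGCATA had no read in cw15_325arg, 2.67 CPM in NO- and 6308 CPM in cc124-.

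By limma, 348 sequences were higher and 240 lower in cw15_325arg at an adjusted p under 0.05, but the simulation with the measured spreads made 615 false calls among 669 here, so the count cannot be relied on. It fell to 0 without any single starved cc124- or gamete library and to 54 without vegetative cc124-, and was 1167 without vegetative NO-, 3433 and 3549 without the first and second cw15_325arg library, and 322 higher and 25 lower with median-of-ratios scaling. The cw15_325arg pair agreed less than the others across sequences, with a Pearson correlation of log2 levels of 0.543 against 0.927 for starved cc124- and 0.947 for gametes. Counts in all 3 pairs differed by far more than sampling noise, with chi-square per degree of freedom of 636, 58.4 and 61.1, so no pair looked like the same library deposited again.

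The nuclei library lacked small RNAs that were abundant in whole cw15_325arg cells and held others that whole cells did not. Its log2 levels had Pearson correlations of 0.216 and 0.345 with the whole-cell libraries of its own strain. They were 0.520 to 0.543 with cc124-, 0.424 to 0.458 with NO- and 0.418 to 0.459 with zygotes. By this measure the library was least like its own strain. The whole-cell cw15_325arg libraries also correlated weakly with cc124- (0.163 to 0.305), but at 0.448 to 0.572 with NO-. The low values for nuclei may therefore reflect those whole-cell libraries as well. The folds below can reflect a mixed or mislabelled sample as well as the cell fraction. TACCGCGGACAACAAGCAGCC had no read in nuclei, at least 10790-fold lower than in whole cells. ACAAGCTTCCCACCACATGACCCGCC and AACAAGCTTCCCACCACATGACCCGCC averaged 9345 and 6084 CPM in whole cells and had no read in nuclei. CTCGACCTGAGCTCAGGCAAGATTAC, from the 5′ end of large subunit ribosomal RNA, had 12267 and 1495 CPM in whole cells and no read in nuclei. TTGACGGGACGGATTTTGCAC averaged 2621 CPM ± 110 (SD, n = 2) in whole cells and had 1 read in nuclei. In nuclei, AGCAGACCCGGGACGCAGTGC stood at 226258 CPM against 45.9 and 45.7 CPM in whole cells, a pooled ratio of 4947.

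Several sequences high in nuclei were those that also marked cc124-. TTGGGCGGCGTTGTAAGATT had 6498 CPM in nuclei and no read in whole cw15_325arg cells, at least 15674-fold higher, and AGCAGAACAGGCGTTCGACGG had 1839 CPM against none, at least 4436-fold higher. TGAGATCAGCGGGGTGGGAGA and TAGCAGGGGCAGCGTGTTCTG had 2527 and 1049 CPM against none. TGCTCACCCTGGACGGCCTCG had 8398 CPM against 6.41 and 0 CPM. By limma, 380 sequences were higher and 2102 lower in nuclei at an adjusted p under 0.05, and 382 were higher and 1224 lower by limma-trend. The count was 1508, 1531, 1556 and 1543 without each starved cc124- and gamete library, and 4965 and 5128 without each whole-cell cw15_325arg library, and simulation with the measured spreads recovered 0 of 100 changes of 16-fold. With 1 nuclei library and so wide a range, this count cannot be relied on, and absence from nuclei refers to the deposited list, from which sequences with few reads might have been removed.

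Size classes were tested as lists. The list of 2852 sequences of 21 nt, fixed in advance, did not pass in any of the 8 comparisons with camera in limma, with adjusted p from 0.272 to 0.787. Adjusted over the list alone, 166 of its members were higher and 1 lower in zygotes, against 160 and 1 over all sequences tested, and in nuclei 180 were higher and 875 lower, against 180 and 880. Lists of 20 nt and 22 nt sequences, added after the data were seen, did not pass either. With the preset correlation alone, the 836 sequences of 23 to 28 nt, also added later, ranked lower as a list than the other sequences in starved cc124- (adjusted p = 2.86e-06), in nuclei (0.000291), in the mean of starvation (0.00255) and in NO- against cc124- (0.00627). They ranked higher in cw15_325arg against the other strains (5.93e-05) and in the gamete response relative to the starvation response (4.87e-05). Each of these 6 list calls was lost with an estimated correlation, with an adjusted p = 0.95 by limma's camera.

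Methylation was measured in cw15_325arg DNA at small RNA sequences, which addresses whether regions that make small RNAs are methylated. Sites of small RNA sequences with at least 10 input reads were enriched in the methylcytosine IP. Over 356 sites with at least 10 input reads, the median log2 ratio of IP to input was 2.07, or 4.20-fold, with quartiles of 1.34 and 2.73. It lay above all 10000 random sets of 18-mers, whose medians had a middle of 0.61 and a central 95% range of 0.23 to 0.95. Random sets matched on input count and GC content came closer, with 1.26 (1.06 to 1.47). At 687 sites called low-copy by their few input reads, the pooled log2 ratio was 0.87. This was percentile 91.2 of random sets (central 95% range -0.43 to 1.18), so no enrichment was detected there. These sites held 389 reads in the counted part of the input, and they need not be single-copy. AATGTAGATAAGGGAAGTCGGC, with 18 input and 185 IP reads, was enriched 11.1-fold (95% interval 6.85 to 19.2), and TGGATTTACGGAAGACGAACAT, with 20 and 195 reads, 10.6-fold (6.66 to 17.7). AACTCTCAACAACGGATATCTTGGCT, from the 5′ end of 5.8S ribosomal RNA, was enriched 7.59-fold, and the 18S fragment TACCTGGTTGATCCTGCCAGTAG 1.90-fold (1.21 to 3.03). Without the recognised rRNA 5′ end fragments, 344 sites kept a median of 2.05. Other parts of ribosomal RNA were not recognised by the motifs. Whether the other enriched sites, including those named here, come from ribosomal RNA was therefore not tested.

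The 3 lowest ratios among the abundant sequences belonged to overlapping sequences high in cc124-, which are not independent sites. TATGGACAATGGACGGCATA had 10 input reads and 1 IP read, a ratio of 0.108 (95% interval 0.00250 to 0.762), and TTTATGGACAATGGACGGCAT had 11 and 5, a ratio of 0.493 (0.134 to 1.54). Across the lists of strain-specific sequences, the 52 NO- specific sites with a DNA read had 194 IP and 55 input reads, an enrichment of 3.82-fold (95% interval 2.82 to 5.26). The 85 cc124- specific sites with a DNA read had 131 IP and 227 input reads, a ratio of 0.625 (0.5 to 0.779). Random sets of tested sites matched on DNA reads and GC content gave medians of 1.64 and 1.30. The NO- list lay above and the cc124- list below all 10000 sets, and leaving out any overlap family kept them between 3.56 and 4.20 and between 0.535 and 0.689. This split by strain was examined after the data were seen.

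**Figure D5:**
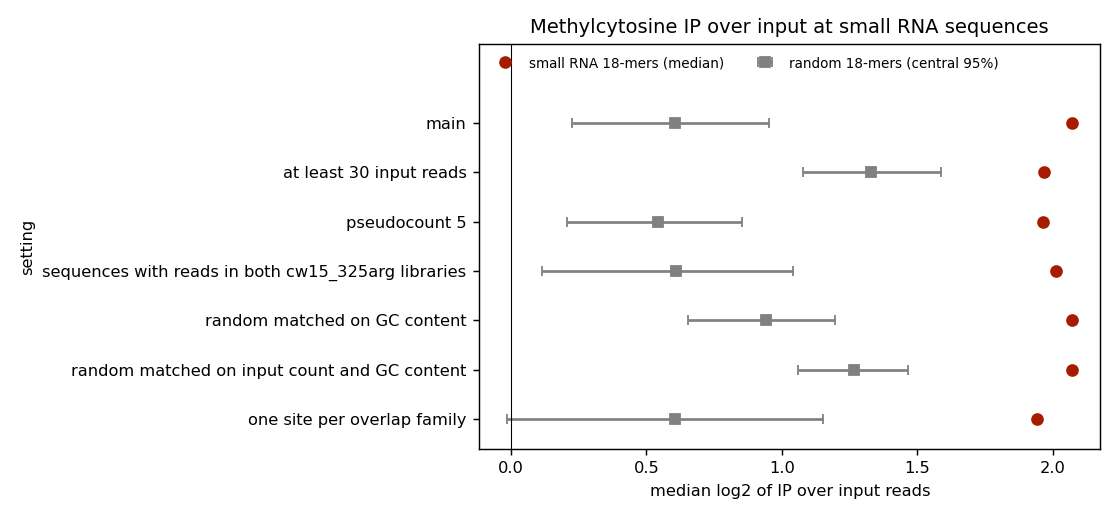
Median log2 ratio of methylcytosine IP to input reads at small RNA 18-mers with at least 10 input reads (circles) under the settings plotted (rows), with the median and central 95% range of 10000 random sets of 18-mers (squares with bars). The small RNA medians lie between 1.94 and 2.07, to the right of every random range plotted, and low-copy sites are not plotted.

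Sites with at least 10 input reads are probably repeated in the genome at this depth, but copy number was not measured. Of the 4289 tested sites, 2232 had no DNA read at all. The IP and input were 1 library each, neighbouring sites overlap, and sequences found in other strains were read against cw15_325arg DNA.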

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

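No test in this part was chosen after its result was seen. The comparisons above used aligned reads alone, while the first vegetative cw15_325arg library also has its reads before alignment. Of 1814880 trimmed reads, 47.1% (exact 95% interval 47.0 to 47.2) are missing from the aligned list, a signal in data that those comparisons did not use, with no control library to set it against. The most frequent unaligned sequence took 168956 reads. Among unaligned reads of 18 nt or more, 40.0% were 21 nt and 39.8% were 20 nt long, and 61.1% of those of 21 nt began with T. After removal of 1 or 2 bases at the 3′ end, 14.2% of unaligned reads matched an aligned sequence, against 5.03% after removal at the 5′ end, so bases added or misread at the 3′ end account for a part at most and the rest stays open. No biological explanation was tested, since the design has no group for it.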

How the results depend on the processing

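Alternatives added after seeing the data were the fits without the cw15_325arg libraries, without rRNA ends in the totals, with overlap families, and without the vegetative NO-, vegetative cc124- or single zygote libraries, all those for NO- against cc124-, and for DNA the low-copy, family and rRNA settings and random sets matched on input count and GC content. The cause of the differences below was not tested, except that families, stricter filters and fewer read lengths leave fewer features. Of 178 comparison values under alternatives, 128 stayed near the main value and 50 moved. For counts of calls the band called near was wide. It took in 2091 calls against 1479 for NO- against cc124-, with no filter beyond 50 reads in all. Of the 128, 59 are counts of 0 against 0 calls for starvation and gametes, which have no direction and show no stability. In 13 of 68 other counts of calls, the side with more calls changed. Of 1199 values for 79 named changes, 1062 still passed, 137 lost the call (133 of them when 1 library was left out) and 0 reversed.

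With limma-trend the calls became 26 for starved cc124-, 8 for the mean of starvation, 437 for zygotes, 1765 for cw15_325arg against the other strains (486 higher, 1279 lower) and 1606 for nuclei. Without the 3 cw15_325arg libraries they were 3 for the mean of starvation, 1412 for zygotes (537 higher, 875 lower), and 1185 higher and 963 lower for NO- against cc124-. With at least 50 CPM they were 107 for zygotes, 879 for nuclei and 509 for NO- against cc124-. With a pseudocount of 2 reads they were 129 for zygotes, 331 for cw15_325arg and 1601 for nuclei. With overlap families they were 96 for zygotes, 260 for cw15_325arg, 767 for nuclei and 495 for NO- against cc124- (270 higher, 225 lower). For cw15_325arg, at least 50 CPM gave 186 higher and 321 lower, reads of 20 to 22 nt gave 359 calls, median-of-ratios scaling gave 347 (322 higher, 25 lower) and totals without rRNA ends gave 310 higher and 328 lower. Median-of-ratios scaling shifted single libraries by up to 1.42 on the log2 scale, the largest in the first cw15_325arg library.

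From 2 h to 6 h in zygotes, totals without rRNA ends left 299 sequences over 10-fold higher and 15 over 10-fold lower. The larger side also changed without the first or second vegetative cw15_325arg library for zygotes (536 higher and 815 lower, 555 and 889), for cw15_325arg (727 and 2706, 931 and 2618) and for NO- against cc124- (1227 and 1012, 1238 and 1011), and without vegetative NO- for cw15_325arg (496 and 671). Leaving out 1 library gave between 0 and 1444 calls for zygotes, 0 and 3549 for cw15_325arg, 1508 and 5128 for nuclei, 0 and 3 for the mean of starvation, and 1043 and 2249 for NO- against cc124-. It kept the median 21 nt share between 55.8% and 57.5%, T as first base between 49.5% and 53.2%, and the share of the 3 rRNA ends between 10.2% and 11.4%. Where an arm kept 1 library, it was assumed to vary like the other groups.

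The median 21 nt share was 27.3% with each distinct sequence counted once and 62.5% without rRNA ends. The median share of rRNA ends, 10.9% of reads, was 0.107% of distinct sequences. The correlation of the cw15_325arg pair was 0.403 over all sequences. The log2 ratio of IP to input over the pooled reads of 687 low-copy sites was 0.87, at percentile 91.2 of random sets, which is another quantity than the median over sites.

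Not run, for want of a genome, were loci, sequences placed up to 20 times, merging within 50 nt, annotation classes, lists by gene or position and DNA reads by number of placements, and both count-model tools were left out, since the plan kept them for deposited columns of counts. No paired analysis was possible because the labels give no replicate numbers shared between groups. Depth limits sequences below 3 counts, between 0.476 and 3.20 CPM per library.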

Other observations

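The tests in this part were chosen after the result was seen, except those on size selection and the splits of the libraries.

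Small RNAs of 21 nt occurred as sense and antisense pairs. In 12 of 12 libraries the most frequent offset between paired 21 nt sequences was the one that leaves 2 nt overhanging at each 3′ end, with 360 such pairs in vegetative NO- against a median of 171 over other offsets. The next most frequent offset was close, at 264 pairs in that library. This is consistent with products of a Dicer cut, as a hypothesis. In zygotes at 6 h there were 1436 pairs with 2 nt overhangs, against a median of 891.

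The nuclei library held 79 of 158 cc124- specific sequences, and whole cw15_325arg cells at most 1.27% of them. A library of cc124- RNA alone is argued against by the NO- specific sequences, whose summed level in nuclei was 9.44% of that in vegetative NO-, where cc124- libraries held at most 0.0395%. Of the nuclei reads in sequences absent from both whole-cell libraries, 52.1% lay in sequences with at least 10 CPM in cc124-. This was close to the bound of 50%, which was set after the data were seen. The share also counts the cc124- specific sequences that raised the question, so it partly restates the pattern and cannot decide it. RNA or reads of other strains mixed into the library may account for the pattern. Those absent sequences held 7.40% of all nuclei reads, and 27.5% of their reads lay in sequences with at least 10 CPM in zygotes and 5.33% in NO-. Retention in the nucleus of small RNAs that cw15_325arg itself makes stays open, because the whole-cell depth cannot exclude them.

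Zygotes held 165 sequences with at least 50 CPM at any of the 3 times and at most 1 CPM in every NO- library. Of these, 54.5% stood at 10 CPM or more at 30 min, and 46.1% were over 4-fold higher at 6 h than at 30 min. The 279 sequences called higher than in gametes, a set chosen on levels that include 30 min, were all over 4-fold above gametes at 30 min, and at 6 h 7 of them were over 4-fold higher and 19 over 4-fold lower than at 30 min, with a median log2 change of -0.82. Small RNAs of the R3+ parent, which has no library here, may account for the early part and new synthesis after mating for the late part, but with no R3+ library and 1 library at each time both stay open. Scaling by the 18S fragment is argued against for the called sequences by the size of its share. All rRNA ends together took at most 14.6% of reads in zygotes and 11.9% in gametes, too little to give changes over 4-fold. With these ends left out of the totals 287 were higher, which adds little, since such shares could hardly have changed the count.

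The 18S fragment fell 32.5-fold between zygotes at 2 h and 6 h. General decay of all ribosomal RNAs alike, as the whole cause, is argued against by the other ends. The 5.8S fragments fell 1.40-fold, and the large subunit ends 2.27-fold (95% interval 1.53 to 3.41, from 83 and 39 reads). Parts of 18S ribosomal RNA beyond its 5′ end were not recognised by the motifs, so decay of 18S as a whole was not tested. Size selection against 23 nt is argued against by the other 23 nt reads, whose fold fall of 0.767 is a rise. A difference between libraries in handling was not tested, and the same fragment differed 15.6-fold between the vegetative cw15_325arg libraries and 2.90-fold between the gamete libraries. A change during zygote development likewise stays untested, with 1 library at each time.

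The absence of cc124- specific small RNAs from whole cw15_325arg cells was set against the DNA of that strain. Of the cc124- specific 18-mers, 65.4% (exact 95% interval 56.5 to 73.5) had a read in the DNA libraries, against 82.5% of the NO- specific and 48.0% of all tested 18-mers. Missing DNA stays open as a cause, because an 18-mer can be read from another copy, the depth is low, and AGAACAGGCGTTCGACGGACA had no DNA read.

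The 3 NO- and 3 cc124- libraries were split in 10 ways, with all other libraries kept in each fit. The real split gave 1709 calls and the highest other split 0, so the real split was the only 1 of 10 with that many. The share cannot fall under 0.05, since the real split is itself 1 of the 10, so this cannot decide the question. For the methylation result, 0% of random sets matched on input count and GC content reached the median of the small RNA sites. This argues against GC content alone as the cause. C followed by G (CG) and the DNA around each site were not matched, so other features of base composition stay open. Reads starting with CG made up 12.1% of IP and 3.59% of input reads, and reads with CG anywhere 85.3% and 88.4%. The matched sets were not run with overlapping sites reduced to families, so their range may be too narrow.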
